A study of Zea mays with 11 samples.

How the data were processed

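The series profiles poly(A) RNA of the maize inbred line Mo17, grown in the field and self-pollinated on a common day, by Illumina RNA sequencing. There were 11 libraries: whole kernels at 3 and 5 days after pollination (DAP), isolated endosperm at 8 stages between 7 and 25 DAP, and ear leaf at 13 DAP as a control. Each stage had 1 library. No stage was replicated, so the spread between plants or library preparations of a stage was not measured.

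The deposited table holds FPKM values (fragments scaled to transcript length and to the mapped total of the library) that the authors calculated for 34145 genes, rounded to 2 decimals. Per the submitters' processing notes, cutadapt, TopHat2 and edgeR were used, with no versions or roles recorded. The genome build, the gene annotation and the counting program are not given in the sources used here. The FPKM values of a library summed to between 273651 and 300271 over the listed genes. Whole read counts could not be recovered from the rounded values, so the sequencing depth of each library is unknown, no counting interval is given, and a value of 0 means only that the gene was listed at 0. No column of per-sample values was left unused.

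Gene identifiers are those of the table. Names were taken from the synonyms of a RefSeq gene table of another assembly, Zm-B73-REFERENCE-NAM-5.0, used for names only; 18367 of the 34145 identifiers matched (53.8%). That gene table holds no product names. The product words of the gene lists were therefore matched to the Arabidopsis description that the authors gave beside 11464 identifiers, which was a departure from the plan. A name such as "Arabidopsis match PCNA" below refers to that description. The 20 gene lists were fixed before the data were examined: starch synthesis, sucrose cleavage, zeins, endosperm transcription factors, ER folding, transfer cells (BETL), aleurone, embryo-surrounding region, embryo, late seed (LEA), photosynthesis, C4 cycle, cell cycle, histones, cytosolic ribosomal proteins, DNA methylation and demethylation, small RNA machinery, families with miRNA targets, Polycomb PRC2 and heat shock. After the data were seen, 7 genes that carry a list symbol as a homonym were left out. Reads of near-identical copies, such as the zein and histone families, can be shared among members by the authors' mapping, so values of their members are uncertain. Some symbols matched more than 1 identifier, and those reported (sbe1, pbf1, met1, meg2, dcl4, ae1 and fl1) are named by identifier.

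Values were analysed as log2(FPKM + 1). A fold change on this scale understates the change of genes with low FPKM. The change over endosperm development was tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) as the slope per day over the 8 endosperm libraries, for the 15149 genes with a mean of at least 1 FPKM over these libraries. The fit leaves 6 residual degrees of freedom, which also absorb any departure from a straight line. A moderated F-test of day and day squared together, with 5 residual degrees of freedom, covered curved changes. It is called the curved test below, although a straight-line change can also pass it. Both tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. "Rose" and "fell" refer to this slope. Libraries taken on different days are not replicates, and the p-values treat departures from the fitted line as the error.

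Gene lists with at least 5 tested members were tested with limma camera at its preset correlation of 0.01, again with an estimated correlation, and with fry. Member counts are given over all genes tested and adjusted over the list alone. Comparisons of 1 library with another have no test. They are described by the log2 ratio of (FPKM + 1), the number of genes at least 4-fold apart, and the percentile of a list's median among 10000 random lists of the same size matched on mean expression in 20 bins. These percentiles describe the libraries and are not p-values.

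Genes were named by a rule fixed before the data were examined: the 8 largest slopes in each direction among called genes with a mean of at least 10 FPKM, with near-identical family members counted as 1 after the second; the 4 members of each list with the highest mean (photosynthesis and C4 cycle: over all 11 libraries); a fixed set of starch, zein, transcription factor and epigenetic genes; the 6 highest and 6 lowest ratios of each library comparison among genes of at least 10 FPKM; and the 4 largest day-squared terms in each direction among genes of at least 10 FPKM without a trend call. At most 2 identifiers without a name were added each way. A family was taken as genes with the same Arabidopsis match or, without one, the same symbol stem, a definition set after the values were seen. Of the fixed set, su1 and su2 were not matched under those symbols. Genes outside the rule are marked as chosen after their values were seen.

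The trend script was tested on simulated data with 200 changed genes among 15149. It recovered 51% of genes with a slope of 0.1 per day and 91% of those with a slope of 0.2, with 6 false calls among 148. The curved test recovered 70% of genes with a day-squared term of 0.02, with 8 false calls among 148. A simulated list of 25 changed genes was called, and 0 of the unchanged lists were called. The simulated noise was independent between genes, so the simulations do not show how the tests behave on correlated genes. In the data the estimated correlations of the 3 lists called by camera were 0.48 (histones), 0.5 (starch synthesis) and 0.58 (transfer cells). Alternatives fixed before the data were examined were other pseudocounts, filters, scalings, time scales, left-out stages and fold thresholds. Alternatives added after seeing the data left out the 9 and 25 DAP libraries together, rescaled the libraries without the 100 highest genes, and kept the homonyms. Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 were used for the remaining steps.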

Results

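Transcript levels were compared across kernel and endosperm development of the maize inbred Mo17, a standard inbred line, with ear leaf as a control tissue. Whole kernels were sampled at 3 and 5 DAP, isolated endosperm at 8 stages from 7 to 25 DAP, and leaf at 13 DAP, with 1 library each. The endosperm is the starch- and protein-storing tissue of the grain. The series title names starch synthesis, microRNAs and DNA methylation. All values are FPKM as deposited, without replicates, and the depth of the libraries is unknown. The number of genes with at least 1 FPKM ranged from 18961 in the 3 DAP kernel to 12507 in the 25 DAP endosperm. Abundant transcripts took a growing share of the endosperm values. The 10 highest genes held 4.5% of the summed FPKM at 7 DAP, 14.2% at 13 DAP and 27.1% at 25 DAP.

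Over the 8 endosperm stages the 8 steepest rises by the naming rule were of zein genes, while 5 of 6 tested transfer cell genes and 25 of 27 tested histone genes fell. Of 15149 genes tested, 1561 rose and 5671 fell with day after pollination, so 21.6% of the calls were rises. A 25 DAP level at least 8-fold above the 7 DAP level was found for 178 of the rising genes, and a level at least 8-fold below it for 759 of the falling genes. The split between rises and falls depended on scaling. Quantile normalization gave 3097 rising and 3215 falling genes (49.1% rising), and upper quartile scaling gave 2759 and 3848 (41.8% rising). The median slope of all tested genes was -0.034 per day as deposited, a median change of -0.61 on the log2 scale from 7 to 25 DAP. That change was -0.01 after quantile normalization and -0.17 after upper quartile scaling. Rescaling without the 100 highest genes, chosen after seeing the data, gave 3167 rising and 3533 falling genes (47.3% rising). Leaving out the 20 and 25 DAP libraries gave 1563 and 3445 (31.2% rising). Of the 5671 falling genes, 3212 still fell after quantile normalization and 3848 after upper quartile scaling. Of the 12 lists tested as sets, 3 were called by camera, 0 with an estimated correlation (smallest adjusted p = 0.73) and 5 by fry (ER folding, transfer cells, histones, heat shock and Polycomb PRC2), which asks only whether a list's genes move 1 way. The fry calls are given for the values as deposited only. There the median slope of all tested genes was itself negative, so a down call by fry can follow from that general fall.

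Zeins, the main storage proteins of maize endosperm, include the highest transcripts of the late stages. The 8 steepest rises by the naming rule were all zein genes: gz50, z1C1_4, fl2, z1A2_1, z1C1_7, z1A1_3, z1A2_2 and z1A1_7. The gz50 transcript went from 0.43 FPKM at 7 DAP to 39.91 at 10 DAP, 2557 at 13 DAP and 12281 at 25 DAP (slope 0.726 ± 0.145 SE per day, adjusted p = 0.0042). The z1C1_4 transcript went from 0.99 to 74.53, 3316 and 9605 FPKM at the same days (slope 0.7, adjusted p = 0.011). The fl2 transcript reached 3115 FPKM at 25 DAP from 0.1 at 7 DAP (slope 0.656, adjusted p = 0.0032). Of the 4 members of the zein list, 3 rose, and 4 when adjusted over the list alone. The list was too small for a set test, and 1 of 4 rose after quantile normalization (fl2), which ended the calls of zp16 (0.078) and zp27 (0.23). The zp16 transcript went from 6.27 FPKM at 7 DAP to 17853 at 20 DAP, the highest value of that library. The zp27 transcript had the highest 7 DAP value of the list, and went from 47.0 FPKM at 7 DAP and 157.4 at 9 DAP to 9561 at 20 DAP and 3276 at 25 DAP. Its call (slope 0.299, adjusted p = 0.049) was lost on leaving out any of the 7, 9, 10, 11, 15 or 20 DAP libraries, with an adjusted p of 0.17 without 7 DAP, 0.091 without 9 DAP, 0.06 without 10 DAP, 0.053 without 11 DAP, 0.062 without 15 DAP and 0.12 without 20 DAP. The zp16 call (slope 0.52, adjusted p = 0.018) was lost without 7 DAP (0.059) or 20 DAP (0.055). The zp15 transcript, at 6.34 FPKM at 7 DAP and 1666 at 20 DAP, did not pass the trend test (adjusted p = 0.055). It passed the curved test (adjusted p = 0.0029). Unnamed identifiers AF546188.1_FG005 and AF546188.1_FG007 rose alongside, to 11651 and 13550 FPKM at 25 DAP. Without the filter on mean FPKM, with 34145 genes tested, the calls of zp16 (0.079), zp27 (0.19) and both unnamed identifiers (0.057 and 0.058) ended.

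**Figure D1:**
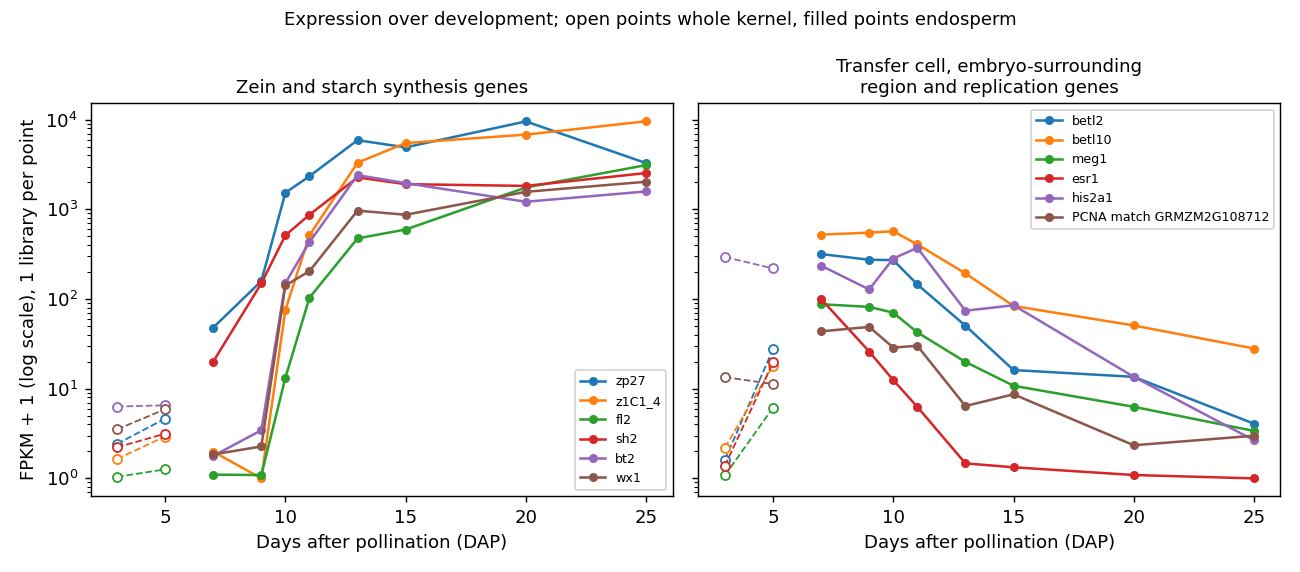
FPKM + 1 on a log scale against days after pollination for 6 zein and starch synthesis genes (left) and 6 genes of transfer cells, embryo-surrounding region, histones and replication (right), with 1 library per point, open for whole kernel and filled for endosperm. On the left, bt2 and wx1 stand at 2.44 and 1.27 FPKM at 9 DAP and at 149.3 and 140.8 FPKM at 10 DAP.

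Of 24 tested starch synthesis genes, 7 rose, 3 fell and 14 were not called, with the same 7 and 3 adjusted over the list alone. The subunits of ADP-glucose pyrophosphorylase, the enzyme that makes the sugar nucleotide for starch, were among the highest. The large subunit gene sh2 stood at 19.01 FPKM at 7 DAP, 148.3 at 9 DAP, 511.4 at 10 DAP and 2270 at 13 DAP (slope 0.296, adjusted p = 0.026). The small subunit gene bt2 went from 0.78 FPKM at 7 DAP to 149.3 at 10 DAP and 2406 at 13 DAP (slope 0.48, adjusted p = 0.036). The granule-bound starch synthase gene wx1, needed for amylose, went from 0.85 at 7 DAP to 140.8 at 10 DAP and 2031 at 25 DAP (slope 0.525, adjusted p = 0.013). Rises were also called for ss1 and du1, which encode soluble starch synthases, and for zpu1, a pullulanase-type debranching enzyme that went from 0.97 FPKM at 7 DAP to 40.95 at 25 DAP. The branching enzyme genes ae1 (GRMZM2G032628) and sbe1 (GRMZM2G088753) and the amyloplast transporter gene bt1 were highest at 13 DAP, at 977.6, 181.3 and 1329 FPKM, and had no linear call (adjusted p = 0.27, 0.11 and 0.23), although all 3 were called in the curved test. The curved calls of ae1 and sbe1 were lost without 7 DAP (0.11 and 0.084), and that of ae1 without the filter on mean FPKM (0.053). The second identifier listed as sbe1, GRMZM2G088737, stayed between 2.12 and 3.22 FPKM in endosperm. Its Arabidopsis match is LAZARUS 1 and not a branching enzyme, although it counts among the 14 list members not called. The remaining riser was the starch synthase 4 match GRMZM2G044744 (3.08 to 10.06 FPKM). The falling members were the starch synthase 2 match GRMZM2G126988 (8.49 to 2.35), the starch synthase 3 match GRMZM2G121612 (2.65 to 1.64) and GBSSIIa (6.22 to 3.85). These 4 were chosen after their values were seen. Under both scalings 1 member fell. The list was higher as a set (median slope 0.05, mean 0.092, camera adjusted p = 0.0022) but was not called by fry (adjusted p = 0.3), with adjusted p = 0.73 with an estimated correlation. Leaving out the 7 DAP library ended the set call (adjusted p = 0.061, median slope 0.004), against 0.0002 to 0.061 over all alternatives. The calls of sh2 and sh1 were lost without the 7 or 20 DAP library (sh2 adjusted p = 0.061 and 0.056, sh1 adjusted p = 0.07 and 0.057), that of du1 without 7 DAP (0.063) or 25 DAP (0.2), and that of bt2 without 7 DAP (0.12), 9 DAP (0.061), 10 DAP (0.05, rounded) or 20 DAP (0.074). Quantile normalization ended the calls of sh2 (0.083), bt2 (0.055) and sh1 (0.06). Without the filter on mean FPKM those of wx1 (0.056), sh2 (0.098), bt2 (0.11), du1 (0.069) and sh1 (0.092) ended. The call of du1 was also lost without 20 and 25 DAP (0.088) or without 9 and 25 DAP (0.16).

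Sucrose-cleaving enzymes, which feed carbon to starch, moved in both directions. The sucrose synthase gene sh1 rose from 5.43 FPKM at 7 DAP to 2127 at 13 DAP and 1952 at 25 DAP (slope 0.357, adjusted p = 0.027). The gene sus1 reached 197.1 FPKM at 11 DAP and fell to 3.5 at 25 DAP (adjusted p = 0.034), and sus2 rose from 1.59 to 38.85 (adjusted p = 0.032). The cell wall invertase gene mn1 fell from 13.27 FPKM at 7 DAP to 1.78 at 25 DAP (adjusted p = 0.011), a call lost without the 25 DAP library (0.24). The calls of sus1 and sus2 were lost without 25 DAP too (0.18 and 0.25), those of sus1 also without 9, 10 or 20 DAP (0.053, 0.059 and 0.095), and those of sus2 also without 7 or 20 DAP (0.11 and 0.062). Both scalings ended the call of sus1 (0.06 after quantile normalization, 0.057 after upper quartile scaling), as did a pseudocount of 5 (0.053), log2 of the day (0.066) and the order of the stages (0.088). Rescaling without the 100 highest genes ended the calls of sus1 (0.063) and mn1 (0.057). Without the filter on mean FPKM the calls of sus1 (0.1) and sus2 (0.096) ended. Without 9 and 25 DAP those of mn1 (0.13), sus1 (0.24) and sus2 (0.29) ended, and without 20 and 25 DAP likewise (0.37, 0.84 and 0.62). Of 9 tested list members 4 rose and 3 fell, the same over the list alone. The others called were neutral invertase matches chosen after their values were seen: GRMZM2G040843 (2.03 to 6.65 FPKM) and GRMZM2G084940 (1.38 to 3.62) rose, and GRMZM2G118737 (4.17 to 0.7) fell. The median slope was -0.006 and the mean 0.014, the set was not called (camera direction up, adjusted p = 0.38), and the median turned positive under quantile (0.029) and upper quartile scaling (0.014).

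Among endosperm transcription factors, o2 went from 0.28 FPKM at 7 DAP to 5.93 at 9 DAP, 45.91 at 10 DAP and 118.8 at 13 DAP. It encodes the bZIP activator Opaque2 of zein genes. Its linear slope missed the threshold (0.258, adjusted p = 0.06), and its curved change was called. The prolamin-box factor gene pbf1 (GRMZM2G146283) went from 3.29 FPKM at 7 DAP to 80.17 at 13 DAP. It had no linear call (adjusted p = 0.072) but passed the curved test (adjusted p = 0.0034). The second identifier GRMZM2G146267 was between 3.64 and 8.19 FPKM. It had no Arabidopsis description, so its place in the list rests on the symbol alone. The gene dof36 was between 12.56 and 34.59 FPKM in endosperm with no call (adjusted p = 0.89). The aleurone regulators nkd1 and nkd2 were highest at 15 DAP for nkd1 (108.2 FPKM) and at 11 DAP for nkd2 (35.47), and stood at 9.28 and 4.03 at 25 DAP. The fall of nkd1 (adjusted p = 0.039) was lost without 10, 11, 20 or 25 DAP (0.07, 0.063, 0.064 and 0.76), and nkd2 had no linear call (0.21). The nkd2 gene passed the curved test (adjusted p = 0.012), but not without 25 DAP (0.31), without 9 and 25 DAP (0.13) or without the filter on mean FPKM (0.062). The nkd1 call also ended under quantile (0.12) and upper quartile scaling (0.11), without the filter on mean FPKM (0.11) and without 9 and 25 DAP (0.56), and its slope was positive (0.134) without 20 and 25 DAP. It ended too on log2 of the day (0.11), on the order of the stages (0.22) and after rescaling without the 100 highest genes (0.14). Of 10 tested members of the list 0 rose and 3 fell (2 over the list alone). The other falling members were mads47 (2.51 to 0.69 FPKM) and vp1 (3.47 to 0.28), both chosen after their values were seen. The median slope was -0.015 and the mean 0.002, and the median turned positive under quantile (0.019) and upper quartile scaling (0.007), where 3 members rose. The set was not called (camera direction up, fry direction down, adjusted p = 0.79 by camera).

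Endoplasmic reticulum folding genes, which serve secretory protein production, were mixed. Of 22 tested members 3 rose and 11 fell (13 adjusted over the list alone). The disulfide isomerase gene pdi was the highest, at 1679 FPKM at 15 DAP, and was not called (adjusted p = 0.29). The calreticulin gene crt2 fell from 867.8 FPKM at 7 DAP to 57.15 at 25 DAP (adjusted p = 0.0017) and bip2 from 82.95 to 9.34 (adjusted p = 0.0032), while bip1 had no linear call (0.063). The bip1 gene narrowly passed the curved test (adjusted p = 0.05, rounded), but not under quantile (0.22) or upper quartile scaling (0.13), among other settings. The bip2 call was lost without 9 and 25 DAP (0.079). The members that rose were o10, an endosperm protein body gene that went from 4.43 to 111.0 FPKM, fl1 (GRMZM2G094532), from 4.21 to 35.13, and the disulfide isomerase match GRMZM2G009157, listed at 0 at 7 DAP and at 2.46 at 25 DAP. All 3 were chosen after their values were seen. The median slope was -0.072 (camera adjusted p = 0.71, fry adjusted p = 0.0012).

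Transfer cell genes, expressed where the endosperm takes up nutrients from the mother plant, mostly fell. The betl2 transcript went from 316.5 FPKM at 7 DAP to 3.07 at 25 DAP (slope -0.379 ± 0.04 SE, adjusted p = 0.00063), betl10 from 521.9 to 27.04 (adjusted p = 0.00067), betl1 from 92.51 to 6.09 (adjusted p = 0.0011) and meg1 from 86.55 to 2.38 (adjusted p = 0.00063). Of 6 tested list members 5 fell and 0 rose (6 fell over the list alone). The fifth was betl3 (7.24 to 2.21 FPKM), and betl4 was not called (adjusted p = 0.074), both chosen after their values were seen. The list was lower as a set (median slope -0.24, camera adjusted p = 0.012, fry adjusted p = 0.0012), with adjusted p = 0.73 with an estimated correlation. The set call was lost without the 25 DAP library (adjusted p = 0.059) and without 9 and 25 DAP (0.1), against 0.0049 to 0.1 over all alternatives. The genes of the embryo-surrounding region fell too: esr1 went from 99.16 FPKM at 7 DAP to listed at 0 at 25 DAP (adjusted p = 0.0069), esr6 from 111.9 to 0.07, esr2 from 49.72 to 0.33 and esr3 from 35.76 to listed at 0. All 4 tested members fell, also over the list alone, and the list was too small for a set test. The libraries are of isolated endosperm and not of single cell types. Neither the share of these cells nor their level per cell was measured.

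Most tested histone genes fell. Among 27 tested histone genes 25 fell and 0 rose, the same over the list alone. The H2A gene his2a1 went from 234.5 FPKM at 7 DAP to 1.66 at 25 DAP (slope -0.379, adjusted p = 0.00081), and the H2B match GRMZM2G401147 from 266.4 to 2.46 (adjusted p = 0.00067). The H2B match GRMZM2G141432 went from 233.2 to 21.56 (adjusted p = 0.0013). The median slope was -0.222 (camera adjusted p = 8.6e-06, fry adjusted p = 0.0024), with adjusted p = 0.73 with an estimated correlation. The 9 and 25 DAP libraries were low for these genes: the median histone log2 ratio was -1.61 from 7 to 9 DAP, 1.07 from 9 to 10 DAP and -1.44 from 20 to 25 DAP. Without those libraries, a choice made after seeing the data, 23 of 27 fell. Without 20 and 25 DAP the calls of his2a1 (0.18), GRMZM2G401147 (0.05, rounded) and GRMZM2G141432 (0.13) were lost. Of 4 tested cell cycle genes 3 fell (4 over the list alone). The genes magi81248 (GRMZM2G108712) and PCNA (GRMZM2G030523), both matches to PCNA, a clamp for DNA replication, went from 42.61 to 1.99 FPKM (adjusted p = 0.0016) and from 19.42 to 0.87 (adjusted p = 0.0036), and the cyclin-dependent kinase B2;1 match GRMZM2G068193 from 14.93 to 0.23 (adjusted p = 0.004). The cytosolic ribosomal protein list held 4 tested genes, all matches to the small-subunit protein SA, and all 4 fell, also over the list alone. GRMZM2G159237 went from 101.5 to 7.26 FPKM (adjusted p = 0.0007) and arpp40 from 45.15 to 7.1 (adjusted p = 0.00073). The arpp40 call and that of GRMZM2G099657 were lost without 20 and 25 DAP (0.08 and 0.087).

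Other steep falls by the naming rule included his2b2 (203.6 to 0.38 FPKM), the H2AX match GRMZM5G883764 (95.52 to 0.25), the GDP-mannose epimerase match GRMZM2G124434 (151.7 to 0.25), thi1-2 (271.9 to 3.32), bap-3b (87.8 to 0.38) and an N-methyltransferase match GRMZM2G170400 (88.41 to 0.85). The his2b2 call was lost without 20 and 25 DAP (0.059). Unnamed GRMZM2G079962 and GRMZM2G437435 fell from 587.1 and 316.7 FPKM to 0.28 and listed at 0.

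**Figure D2:**
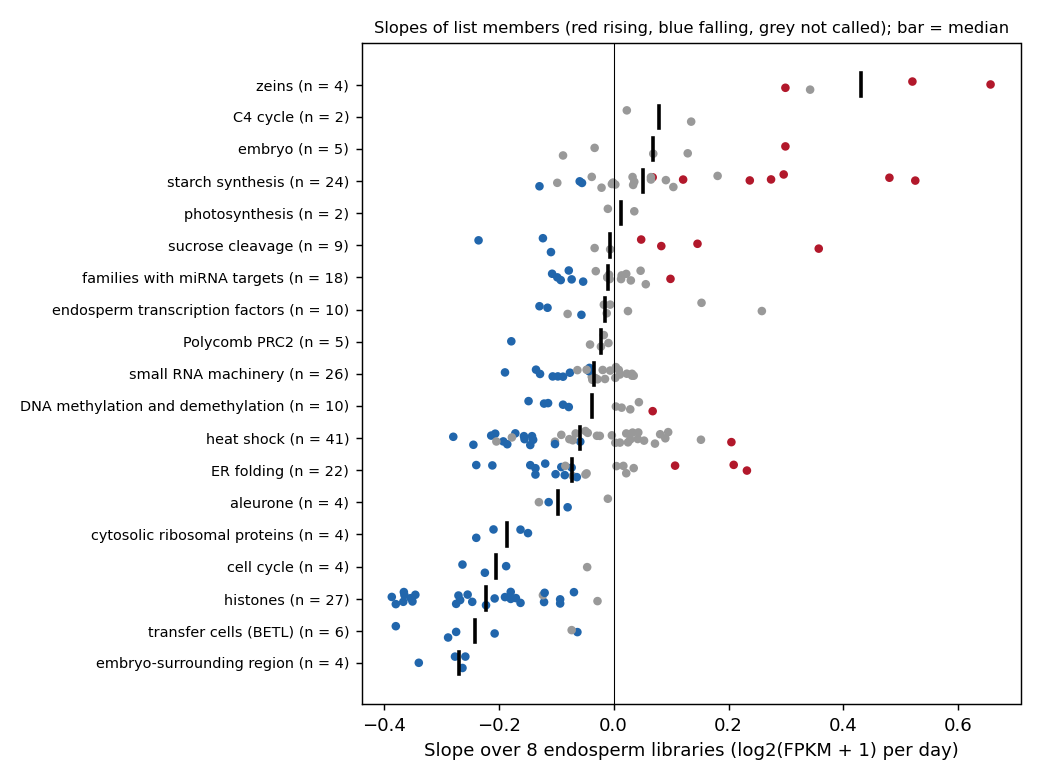
Slope over the 8 endosperm libraries, in log2(FPKM + 1) per day, for each tested member of the 19 lists with any tested member, coloured by trend call, with the list median as a bar. The zein list stands highest with a median of 0.431, and the embryo-surrounding region and transfer cell lists stand lowest at -0.27 and -0.24.

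Of 10 tested DNA methylation and demethylation genes 1 rose and 5 fell, also over the list alone, while 4 rose and 3 fell after quantile normalization and 4 and 5 after upper quartile scaling. Both identifiers listed as met1, a maintenance DNA methyltransferase, fell: GRMZM2G334041 went from 6.63 FPKM at 7 DAP to 2.52 at 25 DAP (adjusted p = 0.019) and GRMZM2G333997 from 1.34 to 0.32 (adjusted p = 0.016), calls that ended under quantile normalization (0.065 and 0.094), for the second without 9 and 25 DAP (0.074), and for the first without 20 DAP (0.057), without the filter on mean FPKM (0.064) or after rescaling without the 100 highest genes (0.051). GRMZM2G333997 had no Arabidopsis description, so that it encodes a methyltransferase rests on the symbol alone. The RNA-dependent RNA polymerase gene mop1 fell from 7.97 to 2.28 FPKM (adjusted p = 0.0043). The chromomethylase gene zmet5, chosen after its values were seen, fell from 9.21 to 1.66 (adjusted p = 0.006). Of the 3 tested genes matched to DEMETER-like 1, DML3 (GRMZM5G828460) was not called (adjusted p = 0.2). GRMZM2G131756, chosen after its values were seen, fell from 6.15 to 1.44 FPKM (adjusted p = 0.0053). GRMZM2G422464 rose from 17.57 to 57.44 FPKM (adjusted p = 0.014), a call lost without 7 DAP (0.051) or 25 DAP (0.2) and without 9 and 25 DAP (0.19). Without 9 and 25 DAP 0 list members rose and 4 fell. Without 20 and 25 DAP the calls of GRMZM2G422464 (0.17), mop1 (0.26) and met1 GRMZM2G333997 (0.21) ended. The DEMETER match GRMZM2G123587 (5.25 to 15.7 FPKM) and dmt106 (11.69 to 18.53) were not called.  The median slope was -0.037 and the mean -0.039, while camera pointed up relative to the other genes (adjusted p = 0.85).

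Small RNA pathway genes gave 0 rises and 9 falls among 26 tested (7 falls over the list alone), with 3 rises and 5 falls after quantile normalization. The argonaute 4 match GRMZM2G089743 fell from 39.13 to 13.1 FPKM (adjusted p = 0.007, lost without 20 and 25 DAP at 0.057), and dcl4 (GRMZM2G160473), SE1B and the argonaute 9 match GRMZM2G469673 had no linear call. The dcl4 gene passed the curved test (adjusted p = 0.031), but not under quantile (0.1) or upper quartile scaling (0.11), among other settings. The set was not called (median slope -0.035, adjusted p = 0.85). Families that hold known targets of microRNAs gave 1 rise and 6 falls among 18 tested, the same over the list alone, and 4 rises and 2 falls after quantile normalization. The riser was ARF2 (2.1 to 9.05 FPKM), chosen after its values were seen. GRF10 fell from 15.8 to 2.31 FPKM (adjusted p = 0.011), a call lost after quantile normalization (0.055), and auxin response factor matches GRMZM2G702026, GRMZM2G137413 and GRMZM2G475263 were not called. The set was not called (median slope -0.009, camera direction up, adjusted p = 0.71), and the median turned positive under quantile (0.024) and upper quartile scaling (0.017). MicroRNAs were not analysed here. Of the 5 Polycomb PRC2 genes, fie1, an imprinted endosperm gene, fell from 53.22 to 7.49 FPKM (adjusted p = 0.0014). The genes mez1, mez2, mez3 and fie2 were not called, so 1 of 5 fell, also over the list alone. The list median was -0.022 (camera adjusted p = 0.72), and 0.014 after quantile normalization. By fry the list moved down (adjusted p = 0.048), on values as deposited. There the median slope of all tested genes was -0.034, lower than the list median of -0.022. The mean slope of the list was -0.053, and camera pointed down without a call.

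Heat shock genes gave 1 rise and 14 falls among 41 tested (0 and 13 over the list alone), with a median slope of -0.058 and no call by camera (adjusted p = 0.96), while fry called the list down (adjusted p = 0.048). Under quantile normalization 4 rose and 10 fell. The riser was the 18.2 match GRMZM2G046382 (7.3 to 74.75 FPKM), chosen after its values were seen. HSP90-2 fell from 553.1 to 62.35 FPKM (adjusted p = 0.002), hsp70-4 from 1269 to 350.2 (adjusted p = 0.0041), the HSC70 match GRMZM2G056039 from 595.8 to 67.4 (adjusted p = 0.0013), and the HSP90.4 match GRMZM2G112165 from 631.7 to 152.6 (adjusted p = 0.025), a call lost without 7 or 20 DAP (0.074 for each), after quantile (0.091) or upper quartile scaling (0.063), without the filter on mean FPKM (0.083) and after rescaling without the 100 highest genes (0.076). The hsp70-4 call was lost without that filter (0.12), without 20 and 25 DAP (0.052) and without 9 and 25 DAP (0.057). The aleurone, embryo and late seed (LEA) lists had few tested members. Of 4 tested aleurone genes 2 fell, cr4 (4.94 to 0.43 FPKM, adjusted p = 0.0025) and sal1 (18.89 to 4.26, adjusted p = 0.028, lost without 7 DAP (0.065) or 25 DAP (0.51)). The sal1 call also ended under quantile (0.17) and upper quartile scaling (0.15), without the filter on mean FPKM (0.069), without 9 and 25 DAP (0.13) and without 20 and 25 DAP (slope -0.006, adjusted p = 0.94). It ended too on log2 of the day (0.054), on the order of the stages (0.12) and after rescaling without the 100 highest genes (0.22). With dek1 and bz1 without a linear call, 3 fell over the list alone. The bz1 gene passed the curved test (adjusted p = 0.019), but not without 7 DAP (0.19) or without the filter on mean FPKM (0.094). Of 5 embryo genes glb2 rose (listed at 0 at 7 DAP, 57.17 FPKM at 25 DAP, adjusted p = 0.00073), and glb1, ole1, ole17 and the oleosin match AC206941.2_FG002 were not called. The ole1 transcript went from 19.15 FPKM at 7 DAP to 121.5 at 10 DAP and 40.52 at 25 DAP. 1 of 5 members rose over the list alone too. The set was not called (median slope 0.069, adjusted p = 0.1), and of the 14 alternatives run it passed only without 11 DAP (0.049). No late seed (LEA) member reached a mean of 1 FPKM in endosperm. The 4 matched genes, dhn1, emb5, the LEA 7 match MGL3 and the LEA 4-2 match GRMZM2G473960, stood at 0.92, 0.96, 2.53 and 2.37 FPKM at 25 DAP. Photosynthesis and C4 cycle lists had 2 tested members each, with 0 linear calls, also over the list alone. The C4 gene ppdk1 passed the curved test (adjusted p = 0.012), but not without 7 DAP (0.15) or without the filter on mean FPKM (0.071).

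The curved test, which a straight-line change can also pass, called 8239 genes, of which 6677 also had a linear call. The remaining 1562 had no linear call (855 with a negative and 707 with a positive day-squared term). The chitinase gene chiB went from 0.31 FPKM at 7 DAP to 282.9 at 20 DAP and stood at 5.74 at 25 DAP. The ribosome-inactivating protein gene b-32 went from 0.57 to 2601 and 111.2 at those days, and the globulin gene glb3 from 2.87 to 1191 and 117.9. The drop after 20 DAP in these 3 genes rests on the 25 DAP library alone, without which they still passed the curved test (adjusted p = 0.0037, 0.0047 and 0.0047). The heat shock 18.2 match GRMZM2G329131 went from 0.62 FPKM at 7 DAP to 78.1 at 15 DAP and 0.09 at 25 DAP. In the other direction, the expansin matches GRMZM2G121308 and GRMZM2G118873 stood at 349.6 and 188.9 FPKM at 7 DAP and were listed at 0 at 25 DAP, and rop9 and the PCaP1 match GRMZM2G007151 stood at 34.72 and 50.79 at 7 DAP, 1.93 and 1.9 at 13 DAP and 6.84 and 18.59 at 25 DAP. Without the filter on mean FPKM the curved calls of GRMZM2G329131 (0.057), GRMZM2G118873 (0.057) and GRMZM2G007151 (0.052) ended.

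From 3 to 5 DAP, transcripts of the embryo-surrounding region and transfer cells were higher in whole kernels. The genes esr1 (0.38 to 18.62 FPKM), esr6 (0.16 to 10.31), betl2 (0.61 to 26.52), the cysteine-rich peptide match GRMZM2G046532 (2.24 to 33.82) and the 2 identifiers listed as meg2 (GRMZM2G088896, 0.27 to 12.66, and GRMZM2G094054, 0.28 to 20.18) were the 6 highest among genes with a name. All 5 measured transfer cell genes and all 5 embryo-surrounding genes were at least 2-fold higher. Their median log2 ratios were 2.5 and 2.8, each at percentile 100 among random lists. The transfer cell list had 7 matched genes. Members such as betl1 (0.21 to 2.81 FPKM) and meg1 (0.08 to 5.13) passed the filter on the mean through the 5 DAP library. ER folding was at percentile 100 too (median 0.24), and starch synthesis (0.21) and zeins (0.94) at 99.9. Histones (-0.27) and the miRNA target families (-0.31) stood at 0.0. The 6 lowest among genes with a name were vp14 (15.84 to 1.36 FPKM), REVEILLE 1 match GRMZM2G421256 (12.28 to 1.33), PR-5 (95.25 to 13.68), OXS3 match GRMZM2G106819 (35.44 to 6.61), homeobox 12 match GRMZM2G117164 (50.62 to 7.56) and SPX3 match GRMZM2G065989 (16.65 to 2.39). In all, 71 genes were at least 4-fold higher at 5 DAP and 32 at least 4-fold lower.

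Isolated endosperm at 7 DAP differed far more from the 5 DAP kernel, with 521 genes at least 4-fold higher and 1626 at least 4-fold lower. Tissue and stage change together here and cannot be told apart. Higher genes included fl3 (11.8 to 1014 FPKM), the globulin gene leg1 (1.22 to 83.02), hag (5.02 to 257.6), hsp22 (3.28 to 182.7), and the auxin biosynthesis genes yuc (0.19 to 44.3) and TA1 (1.54 to 117.0). Lower genes included the beta-glucosidase gene glu1 (276.2 to 0.51), BX4 and BX5 of benzoxazinoid defence synthesis (101.1 to 0.39 and 106.4 to 0.28), EXPA5 (154.8 to 0.42), Amy2 (102.9 to 0.33) and plr354a (222.8 to 2.35). Of the lists, transfer cells (median log2 ratio 3.68), embryo-surrounding region (3.29), endosperm transcription factors (1.36), heat shock (0.97) and embryo (2.62) stood at percentile 100, and the miRNA target families at 0.2 (median -1.1). The embryo list had 3 measured members of 5 matched. Its members ole1 (0.23 to 19.15 FPKM) and glb1 (0.09 to 4.01) passed the filter on the mean through the 7 DAP library, so its median is partly built in.

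**Figure D3:**
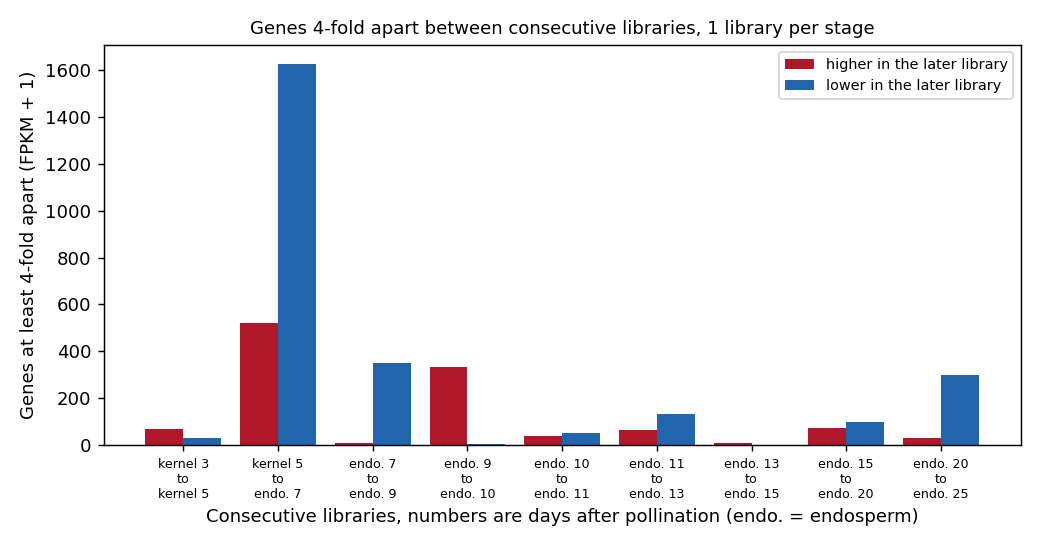
Number of genes at least 4-fold apart in FPKM + 1 between consecutive libraries, higher (red) and lower (blue) in the later library, with 1 library per stage. The step from the 5 DAP kernel to the 7 DAP endosperm holds 521 and 1626 genes, and the step from 13 to 15 DAP holds 11 and 2.

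Between consecutive endosperm libraries the largest steps were those that involve the 9 or the 25 DAP library, which stood apart together: 646 genes were at least 2-fold lower in both than in the neighbouring stages, where 102 would be expected for independent lists. From 7 to 9 DAP 11 genes were at least 4-fold higher and 352 lower, and from 9 to 10 DAP 333 were higher and 6 lower. From 10 to 11 DAP, also 1 day apart, 91 genes differed, and 13 differed from 13 to 15 DAP. From 11 to 13 DAP 199 differed, from 15 to 20 DAP 171, and from 20 to 25 DAP 330 (29 higher, 301 lower). Spearman correlations across genes were 0.875 for 9 to 10 DAP and 0.942 for 10 to 11 DAP, with genes not independent replicates. From 9 to 10 DAP the zein list had a median log2 ratio of 4.24, the starch synthesis list 0.91, the embryo list 2.97, the endosperm transcription factors 0.79 and the histones 1.07, each at percentile 100. From 11 to 13 DAP histones had a median of -1.93 and zeins 2.03. Summed over the 7 endosperm steps, the consecutive stage changes totalled 1506, and 7436 with a pseudocount of 0.1 or 428 with a pseudocount of 5. A gene that changed in several steps is counted in each, so these are not numbers of different genes.

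At 13 DAP the leaf and endosperm libraries differed in photosynthesis and storage genes. Of all genes, 3476 were at least 4-fold higher in leaf and 1257 at least 4-fold lower. Among genes with a name, the highest in leaf were bss1 (2517 FPKM against 0.03), the light-harvesting match AC207722.2_FG009 (1176, endosperm listed at 0), the CP12 match GRMZM2G480850 (1097, endosperm listed at 0), ppc1, the phosphoenolpyruvate carboxylase of the C4 cycle (932.1, endosperm listed at 0), the ferredoxin 2 match GRMZM2G043162 (865.9 against 0.03) and Cab-m7 (868.9 against 0.11). All 43 measured photosynthesis genes were at least 2-fold higher in leaf (median log2 ratio 5.72, percentile 100), as were all 4 C4 genes (7.92, percentile 99.8). Of 52 matched photosynthesis genes only 2 had a mean of at least 1 FPKM over the endosperm libraries. The filter thus let members in mainly through leaf, and the count of 43 is partly built in. The C4 gene ppdk1 was also high in endosperm, at 269.4 FPKM against 968.3 in leaf, and reached 299.3 at 15 DAP. Lowest in leaf among genes with a name were zein genes and hag: zp16 (8466 FPKM in endosperm), zp27 (5904), hag (3802), z1C1_4 (3316), z1A2_1 (2836) and gz50 (2557), all at 0.16 FPKM or less in leaf. The unnamed AF546188.1_FG007 and AF546188.1_FG005, at 5732 and 4815 FPKM in endosperm, were listed at 0 in leaf. All 6 transfer cell genes were at least 2-fold lower (median -4.98, percentile 0.0). Members such as betl1 (55.71 FPKM in endosperm, 0.05 in leaf) passed the filter on the mean through endosperm, so this count is partly built in too. Of 28 starch synthesis genes 14 were at least 2-fold lower and 6 higher (median -0.65, percentile 2.7). Leaf lay outside the range of all 8 endosperm libraries for 58.4% of 16749 genes, where 22.2% would be expected if the leaf were a ninth draw. It was at least 4-fold above the highest endosperm library for 1881 genes and at least 4-fold below the lowest for 327. The 22.2% gives no test, since the endosperm libraries are ordered stages of the same tissue and not interchangeable draws. The 16749 genes were also filtered on the mean over leaf and endosperm, so genes could enter through leaf.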

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

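Leaving out the 9 and 25 DAP libraries together, rescaling without the 100 highest genes, and keeping homonyms were chosen after seeing the data. The counts of 1561 rising, 5671 falling and 8239 endosperm curved change genes (all those that passed the curved test) moved by less than 1.5 times under the other settings run, except as follows. A mean of at least 5 FPKM gave 973, 3139 and 4738, with 7932 genes tested in place of 15149. Rising and falling genes numbered 3097 and 3215 after quantile normalization and 3167 and 3533 after rescaling without the 100 highest genes. Upper quartile scaling gave 2759 rising genes, and omitting 20 and 25 DAP gave 3445 falling ones. Leaving out 1 stage at a time gave 1173 to 1523 rising, 4487 to 5534 falling and 6763 to 8537 curved genes, and without 9 and 25 DAP there were 1249, 5123 and 7528. The number of lists called by camera was 2 to 4 across its alternatives. Of 73 called named genes, 40 lost their call or reversed in 0 of the alternatives that tested them, and 68 of the 73 were tested at a mean of at least 5 FPKM. Testing without the filter on mean FPKM ended 20 of these calls, leaving out 20 and 25 DAP ended 18 and reversed 3, quantile normalization and leaving out 9 and 25 DAP ended 14 each, leaving out 20, 7 or 25 DAP alone ended 13, 12 and 11, rescaling without the 100 highest genes ended 8, and upper quartile scaling and the order of stages ended 6 each. Without 20 and 25 DAP the slopes of nkd1 (0.134), TA1 (0.052) and GRMZM2G046532 (0.054) reversed sign, with fewer samples, and 0 of these 3 passed the threshold.

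For leaf against endosperm at 13 DAP, higher in leaf were 3476 genes as reported, 6451 with a pseudocount of 0.1, 1443 with 5, 6620 at 2-fold and 2311 among genes of at least 10 FPKM. For leaf against endosperm at 13 DAP, lower in leaf were 1257 as reported, and 2898, 486, 3569 and 834 at those settings. The whole kernel at 5 against 3 DAP gave 103 genes as reported, and 474, 21, 772 and 67. For whole kernel stages against endosperm, endosperm 7 against kernel 5 DAP gave 2147 as reported, and 5663, 616, 7753 and 1308. Summed over the steps, the consecutive stage changes in endosperm totalled 1506 as reported. They totalled 7436, 428 and 10176 at the pseudocounts of 0.1 and 5 and at 2-fold, with a gene counted in each step where it changed. Beyond the changes that follow from fewer genes, fewer samples or a lower fold, the cause was not tested. Depth is unknown and limits low genes most: 45 genes were listed at exactly 0.01 FPKM at 20 DAP, 163 at 25 DAP, 257 at 9 DAP and 899 at 7 DAP. No paired analysis was possible because each stage had 1 library.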

Other observations

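Of the tests below, the contrast of long and short products was set out before its result was seen, though after the shared departure it addresses had been noticed, and the other tests were chosen after the result was seen. Some heat shock genes were high at 10 DAP, of which 4 are given, chosen after their values were seen. At 10 DAP the gene hsp101 stood at 115.2 FPKM, against 4.66 at 9 DAP and 12.87 at 11 DAP. The class II gene hsp18f stood at 202.3 FPKM against 3.28 and 19.53, Hsp70 (GRMZM2G310431) at 639.6 against 85.84 and 146.3, and the 18.2 match AC208204.3_FG006 at 495.6 against 5.54 and 125.2, with 502.9 at 20 DAP. The heat shock list had a median log2 ratio of 0.44 from 9 to 10 DAP (percentile 100 among random lists) and -0.66 from 10 to 11 DAP (percentile 0.0). From 9 to 10 DAP 16 of 42 measured members were at least 2-fold higher and 4 lower, and abundant members went down, such as HSP90-2 (751.9 to 433.0 FPKM), HSP90-1 (534.3 to 254.3) and GRMZM2G112165 (979.2 to 405.9). The zein, starch synthesis, embryo, endosperm transcription factor and histone lists were at percentile 100 in that step too. In leaf the 4 genes stood at 271.1, 285.4, 567.0 and 1365 FPKM, above their 10 DAP endosperm values except for Hsp70. Of 45 measured list members, 28 were at least 2-fold higher in leaf than in 13 DAP endosperm (median 2.1, percentile 99.9).

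The 9 and 25 DAP libraries departed together from their neighbours: across 15149 genes, which are not independent replicates, the departure at 9 DAP from the mean of 7 and 10 DAP correlated with the change from 20 to 25 DAP (Pearson 0.56, against 0.02 and -0.07 for 9 DAP with 13 and 15 DAP, and -0.1 and 0.17 for 25 DAP with 11 and 13 DAP), and 646 genes were at least 2-fold lower in both, where 102 would be expected for independent lists. Lower depth of these libraries is argued against for the 2626 genes with a mean of at least 20 FPKM, where the correlation was 0.6, and stays open for lower genes, since 28.9% of genes were listed at 0 at 9 DAP (18.5% at 7 and 19.8% at 10 DAP) and 32.8% at 25 DAP (30.1% at 20 DAP), while genes listed at 0.01 FPKM were fewer at 9 DAP (257, against 899 and 499) and more at 25 DAP (163, against 45). A loss of reads from short transcripts may contribute, since products known to be long lay above short ones by 0.34 at 9 DAP and 0.54 at 25 DAP, outside the relabelled ranges of -0.18 to 0.18 and -0.21 to 0.21, for 78 genes in each class. The median departures of short and long products were -0.17 and 0.17 at 9 DAP, and -0.11 and 0.43 at 25 DAP. At 25 DAP the difference thus lay mostly in the long class, and the short class departed by -0.11 at 13 DAP too. The classes came from product words and hold some misplaced members, and differences also lay outside the relabelled range at 11, 13 and 15 DAP (-0.1, 0.13 and -0.26), whose departures use neither library, so a difference by class is not particular to 9 and 25 DAP. A developmental change shared by 9 and 25 DAP was not tested and stays open.

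More genes fell than rose over the endosperm stages, and a growing share of the values held by a few abundant genes may contribute to this. After rescaling without the 100 highest genes, 47.3% of calls were rises in place of 21.6%, while rescaling each library with all genes kept gave 20.2%. Relative values cannot show whether the abundant genes gained transcripts or the other genes lost them. Whether total RNA per cell changed with stage was not tested.

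The starch synthesis list stepped up between 9 and 10 DAP by a median log2 ratio of 0.91 (higher for 21 of 24 genes), after 0.79 from 7 to 9 DAP (21 of 24). Over 7 to 10 DAP the median was 1.8, and over 9 to 11 DAP it was 1.38. How much of the step comes from the 9 or the 10 DAP library was not settled by these values, since ratios that leave a library out do not test it.

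Whether the trend counts could come from an arbitrary order of stages was tested by reordering them. Among 100 orders including the real one, 1 called as many as 7232 trend genes, the real one, and the highest other called 5023, in an order correlated at -0.72 with day, while 98 called 0. For the curved test 1 order reached 8239, the highest other called 5578, and 92 called 0. For both counts the real order thus called the most genes of the orders drawn. Neighbouring stages resemble each other, so any gradual drift over the libraries would favour the real order. The reordering therefore cannot tell what the drift comes from.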
